A study of Homo sapiens with 6 samples.

How the data were processed

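The 6 human libraries comprised 3 of DU145 cells carrying an empty lentiviral vector and 3 of cells carrying Flag-SRRM4, grouped by the sample titles. Per the labels' protocols, virus was packaged in 293T cells, infected cells were selected with blasticidin for 3 weeks and pooled without cloning, total RNA was extracted with the mirVana kit, cDNA was made from 100 ng of RNA, and AmpliSeq libraries were barcoded, pooled in equal amounts and sequenced on an Ion Proton. The panel reads 1 amplicon per gene. The deposited table holds RPM values, reads per amplicon scaled by the authors to a total of 1e+06 per library, as the column sums show, and rounded to 3 decimals. Reference builds GRCh37 and hg19 are named in the submitters' processing notes, and the aligner, the counting tool and any filter on reads are not given in the sources used here. Reads from 1 amplicon are sensitive to sequence differences under the primers and to which part of a transcript is made, so a gene's level is comparable between libraries and not between genes.

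In each library the RPM values were whole multiples of the worth of 1 read (tolerance 0.1 reads), and whole reads were recovered for 100% of the values. This gave 12384247 to 16857612 reads in the controls and 16018234 to 16143637 in the SRRM4 libraries, with 1 read worth 0.0593 to 0.0807 RPM. The 10 most abundant genes took 4.74% to 5.81% of the reads of a library. Limits for genes at 0 reads were set at 3 reads over the pooled reads of a group. Ratios with 1 to 3 reads in a group carry exact 95% binomial intervals of the counts, and limits and intervals cover counting error only. Other folds are ratios of pooled reads per pooled depth. The table has 20812 amplicons. In it 28 gene names had been turned into dates by a spreadsheet, and 27 of these were restored from the deposited gene identifiers. A RefSeq gene was matched for 19928 amplicons through symbols and older symbols. The reference given is a later assembly than the one used for the reads, so it served only for gene names and for the order of neighbouring genes, and no coordinates are given. Levels of Y-linked genes and of the X-inactivation transcripts are not reported here, and these genes were left out of the named genes. They served only in a check for mixed-up samples, which is given as a count.

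The main test used log2(RPM + 1) of genes with at least 1 RPM in at least 3 of the 6 libraries, fitted with limma 3.58.1 (lmFit, eBayes with a mean-variance trend, two-sided, group as the only term) in R 4.3.3. P-values were adjusted by Benjamini and Hochberg over the tested genes, and an adjusted p below 0.05 was called. Fold changes on this scale understate the change of genes with low values. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 8.54 to 16.0 within groups and 243 to 289 between groups. Amplification can also give such an excess within groups, so it does not show that replicates are separate cultures. No pair was counted as 1 sample, which rests on the labels. Gene lists were tested with limma's camera at a preset correlation of 0.01, if at least 5 members were tested, with p-values adjusted over 21 lists, and again with an estimated correlation. With an estimated correlation camera also uses far fewer degrees of freedom, so a call can be lost without a higher correlation. The lists, 23 in number, were fixed before the data were examined. They cover neuroendocrine, REST-repressed, neural transcription factor, stem cell, SRRM4-dependent, splicing, luminal prostate, basal, junction, mesenchymal, fibroblast, haematopoietic, S phase, mitosis, histone, ribosomal, interferon, NF-kB, MAPK, Notch, hypoxia and glycolysis, sterol and endoplasmic reticulum stress genes. Listed genes without a row under a matching name included NEUROD2, UTF1, TJP3 and CD24. The single value of SRRM4 was also compared by an exact permutation test.

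Named genes followed a rule set at the same time. It takes SRRM4, then the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, then up to 4 members per list with the smallest p, and always a fixed set that includes REST, SOX2, PHF21A, MEAF6, CHGA, SYP, ENO2, NCAM1, PTBP1, ESRP1 and SRRM3. Some genes that the rule takes are not reported here. Any other gene is said to have been chosen after its value was seen. Alternatives were other pseudocounts, filters, rescalings, variance models and thresholds, the replicate number as a block, leaving out each library, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. The test was run on simulated reads for SRRM4 against control with known changes, where 12519 genes were tested. It recovered 62% of genes changed 1.5-fold, 94% changed 2-fold and 100% changed 4-fold or 8-fold, and called 8 of 12319 unchanged genes. Neighbouring genes were compared with 1000 shuffles of gene order. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for tables, exact tests and plots.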

Results

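The series measured gene expression in DU145 cells, an androgen-independent human prostate carcinoma line that was established from a brain metastasis. The cells had been transduced with lentivirus carrying either an empty vector (control, 3 libraries) or Flag-tagged SRRM4 (SRRM4, 3 libraries). SRRM4 is a neural-specific splicing factor that promotes the inclusion of neuronal microexons. Its expression is known from neuroendocrine prostate tumours. Virus had been packaged in 293T cells, a human embryonic kidney line, and transduced pools had been kept under blasticidin for 3 weeks. The labels describe 3 independently repeated experiments per condition on pooled polyclonal cells but do not say whether the transduction was repeated, so p-values measure the spread between these samples only. Expression was read with an AmpliSeq transcriptome panel, which amplifies 1 short segment per gene, and the values give gene levels but no exon inclusion. The control libraries held 12384247, 16857612 and 14857010 reads and the SRRM4 libraries 16018234, 16069892 and 16143637. Of 20812 amplicons, 14405, 14617 and 14602 had a read in the controls and 15280, 15167 and 15292 in the SRRM4 libraries. Over a whole group, 0 reads allowed up to 0.068 RPM (reads per amplicon scaled to a total of 1e+06 per library) in the controls and 0.0622 RPM in the SRRM4 libraries. These limits cover counting error only, because amplified reads carry no molecular identifiers.

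The transduced gene itself separated the groups. SRRM4 (amplicon AMPL21436225) had 0 reads in each of the 3 control libraries, and 341, 354 and 315 RPM in the SRRM4 libraries (337 ± 19.5 RPM, SD, n = 3). Against the limit set by 0 reads in the pooled controls it was at least 4947-fold higher. The exact two-sided permutation test of 3 values against 3 gave p = 0.1, the smallest p that this design allows, and the fitted log2 fold change was 8.40 ± 0.10 (SE, adjusted p = 6.29e-12, limma). Whether the amplicon lies in the transduced coding sequence or reads the cells' own transcript as well was not examined here.

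The comparison of SRRM4 with control cells was set up to ask which genes change when a prostate adenocarcinoma line carries SRRM4. Most measured genes differed. Of 12724 genes tested, 10009 changed (78.7%), 5645 of them higher and 4364 lower in the SRRM4 libraries, at an adjusted p below 0.05 in limma's moderated test. At least 2-fold changes on the log2(RPM + 1) scale were found for 4478 genes (2507 higher, 1971 lower). At least 32-fold changes were found for 70 genes that rose and 106 that fell. The 3 values of one group lay entirely on one side of the other group's 3 values for 10122 genes (79.6% of those tested, against 10% by chance). Replicates were close to each other, with Spearman correlations across genes of 0.995 within the controls and 0.992 to 0.996 within the SRRM4 libraries. Between the groups the correlation was 0.81. A check for mixed-up samples found that 3 of the 6 libraries did not match the labelled cell line. The doubt about identity is shared by all 3 SRRM4 libraries, so cell identity and SRRM4 cannot be separated. The gene groups below are to be read beside that count, and rises and falls are differences between the groups, not effects assigned to SRRM4. Trimmed-mean (TMM) rescaling lowered the median log2 fold change of all tested genes by 0.116, from 0.13 to 0.02, and the share of changed genes that were higher from 56.4% to 50.7%.

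**Figure D1:**
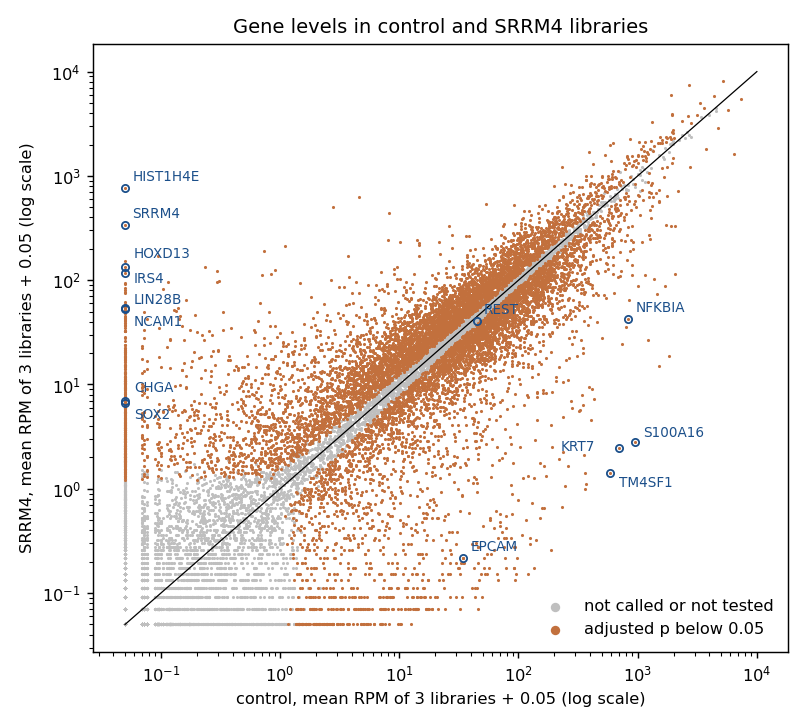
Mean RPM of 3 SRRM4 libraries against mean RPM of 3 control libraries for each gene, both on log axes after adding 0.05 so that genes at 0 reads can be drawn. Coloured points are the genes past an adjusted p of 0.05. NCAM1, LIN28B, IRS4 and HOXD13 stand at 0 reads in the controls, and KRT7 and TM4SF1 fall from 695 and 590 RPM to 2.42 and 1.37 RPM.

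The largest rises were of genes that the controls expressed little or not at all. HOXD13, a posterior homeobox gene, had 0 reads in the controls and 134 ± 17.3 RPM in the SRRM4 libraries (SD, n = 3). IRS4, an insulin receptor substrate, went from 0 reads to 116 ± 8.88 RPM, and GTSF1, a germline piRNA pathway gene, from 0 reads to 93.9 ± 9.26 RPM. Against the limit of 0 reads these genes were at least 1971-fold, 1705-fold and 1380-fold higher. The gap junction gene GJA1 rose from 0.68 ± 0.227 to 191 ± 5.22 RPM, and the Hedgehog pathway transcription factor GLI3 from 0.183 ± 0.0774 to 135 ± 14.9 RPM. AMOT, which encodes angiomotin, rose from 4.52 ± 0.626 to 627 ± 61.4 RPM. The oncofetal RNA-binding protein gene IGF2BP1 rose from 1.04 ± 0.449 to 213 ± 7.49 RPM, and the developmental transcription factor DACH1 from 0.244 ± 0.174 to 123 ± 10.5 RPM. The near-identical mitochondrial creatine kinase genes CKMT1A and CKMT1B reached 154 ± 13.3 and 171 ± 12.7 RPM, with 0 and 2 control reads, and their amplicons cannot be taken as separate measurements. The histone genes HIST1H4E and HIST1H3J complete the 12 largest rises and are described with their family. The largest adjusted p among the 12 was 7.14e-11 (limma), for IGF2BP1.

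The largest falls included 3 keratin genes. KRT7 and KRT19, keratins of simple epithelia, fell from 695 ± 9.42 to 2.42 ± 0.476 RPM and from 370 ± 20.8 to 1.06 ± 0.283 RPM. Another keratin gene, KRT80, fell from 135 ± 2.66 RPM to 0.124 ± 0.0625 RPM. The calcium-binding S100 genes S100A16 and S100A6 fell 347-fold and 513-fold, and the tetraspanin-like surface protein gene TM4SF1 fell 432-fold. Receptors among these genes were LTBR, the lymphotoxin beta receptor (358 ± 30.01 to 0.953 ± 0.292 RPM), and OSMR, the oncostatin M receptor (363 ± 19.9 to 1.37 ± 0.533 RPM). The membrane repair gene MYOF fell 172-fold and EPDR1 fell 373-fold. RPL31P11 is a processed pseudogene and HIST1H1B a linker histone, and reads of close relatives can be assigned to either. The largest adjusted p among the 12 falls was 1.17e-09 (limma), for MYOF. The 12 genes kept 0.0923% (KRT80) to 0.582% (MYOF) of their control level. A small share of control-type RNA or cells in the SRRM4 libraries, left open under the other observations, could set such residual levels. These folds and similar ones below may then reflect that share and not the level of each gene.

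Neuronal and neuroendocrine genes that passed the filter were mostly higher in the SRRM4 libraries. A gene absent from one group was tested only if the other group expressed it, so the filter itself favours changed members, and counts at 1 RPM in the controls and medians without the filter are given. Of 23 tested genes known as targets of the neuronal repressor REST, 19 rose, 3 fell and 1 was not called, with a median log2 fold change of 2.06 (2.58 with genes at 0 reads set to their bound). The stathmin gene STMN3 rose from 1.78 ± 0.172 to 69.0 ± 5.72 RPM, and the synaptic vesicle genes SYP and UNC13A from 1.42 ± 0.385 to 13.8 ± 1.26 RPM and from 0 reads to 11.5 ± 1.20 RPM. Of the 10 at 1 RPM or more in the controls, 6 rose, 3 fell and 1 was not called, and without the filter the median of 36 members was 0.88 (camera adjusted p = 0.00196). TUBB3, the neuronal tubulin, went the other way, from 103 ± 1.45 to 10.1 ± 0.402 RPM. The list differed from all other genes in camera's competitive test (adjusted p = 0.000546, and adjusted p = 0.043 with an estimated correlation). Of 13 tested transcription factors of neural lineages, 12 rose and 1 fell (median 2.64, 3.04 with zeros at their bound, camera adjusted p = 0.000199, and adjusted p = 0.043 with an estimated correlation). Only 4 of the 13 were at 1 RPM in the controls, of which 3 rose and 1 fell, and without the filter the median of 27 members was 0.47 (camera adjusted p = 0.00336). POU3F2, also called BRN2, rose from 0.424 ± 0.223 to 28.4 ± 1.37 RPM, while POU3F3 and ISL1 went from 0 reads to 16.3 ± 0.286 and 15.5 ± 1.87 RPM. POU4F1 had 3 control reads against 298, a ratio of 90.8 (95% counting interval 30.8 to 443).

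Of 17 tested neuroendocrine markers, 13 rose, 3 fell and 1 was not called (median 1.89, 1.96 with zeros at their bound). Of the 8 at 1 RPM in the controls, 4 rose, 3 fell and 1 was not called, and without the filter the median of 27 members was 0.72 (camera adjusted p = 0.017). The adhesion molecule NCAM1, also called CD56, had 0 reads in the controls and 52.5 ± 8.02 RPM in the SRRM4 libraries, at least 772-fold higher. Chromogranin A (CHGA) went from 0 reads to 6.85 ± 2.16 RPM, and the neuronal enolase ENO2 from 22.2 ± 0.474 to 29.4 ± 2.05 RPM. SRRM3, a relative of SRRM4, had 1 control read and 127 reads in the SRRM4 libraries, a ratio of 116 (95% interval 20.5 to 4622). PEG10 and UCHL1, which belong to the same list, fell 116-fold and 4.49-fold. Camera gave the list an adjusted p of 0.0146, and adjusted p = 0.196 with an estimated correlation. Among 12 tested genes of pluripotent and neural stem cells, 8 rose, 1 fell and 3 were not called (median 0.79). At 1 RPM in the controls were 7, of which 3 rose, 1 fell and 3 were not called. Without the filter the median of 23 members was 0.33 and the call was lost (camera adjusted p = 0.0516). LIN28B, a let-7 inhibitor, went from 0 reads to 54.6 ± 4.68 RPM and SOX2 from 0 reads to 6.57 ± 0.349 RPM, and the neural RNA-binding protein gene MSI1 rose 11.9-fold. Camera gave adjusted p = 0.039 for this list. It gave adjusted p = 0.19 with an estimated correlation, although the estimate (-0.084) lay below the preset 0.01. That call was also lost without SRRM4 replicate 3 (camera in limma, adjusted p = 0.061, within a range of 0.00769 to 0.19 over all alternatives). The mismatch of 3 of the 6 libraries with the labelled line bears on all 4 of these lists.

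**Figure D2:**
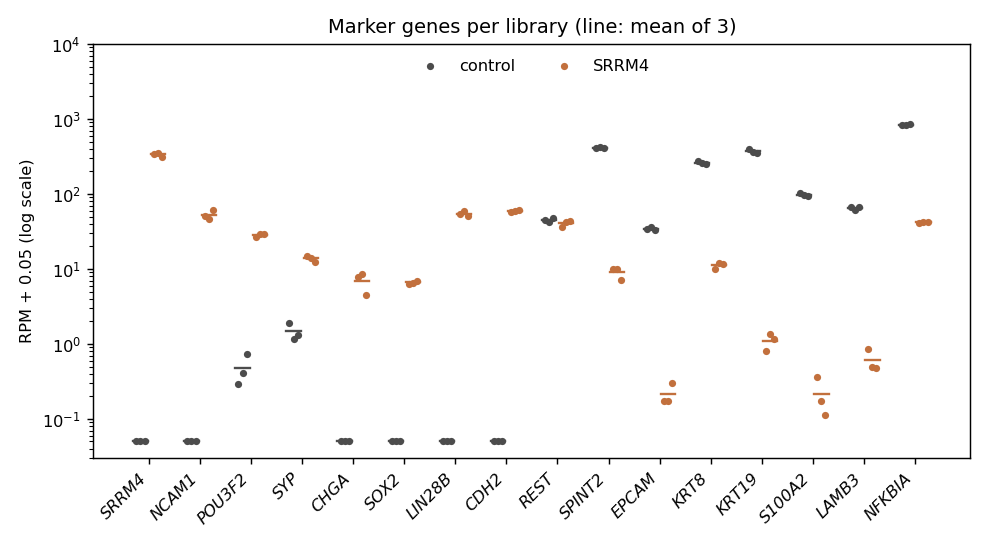
RPM of 16 genes in each library, on a log axis after adding 0.05, with control libraries in grey, SRRM4 libraries in orange and a line at the mean of 3. SRRM4, NCAM1, CHGA, SOX2, LIN28B and CDH2 stand at 0 reads in every control library, REST is at 44.7 and 40.7 RPM, and the epithelial genes to its right are lower in every SRRM4 library.

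Genes whose exons are reported to depend on SRRM4 did not move together at the gene level. Of 18 tested, 8 rose, 7 fell and 3 were not called, and the list did not pass camera's test (adjusted p = 0.908, and adjusted p = 0.915 with an estimated correlation). Their median log2 fold change was -0.04, while the mean, 0.19, and the direction of the test were positive. REST, whose splicing SRRM4 is known to change, had 44.7 ± 2.99 RPM in the controls and 40.7 ± 3.63 RPM in the SRRM4 libraries (log2 fold change -0.14 ± 0.10, SE, adjusted p = 0.224, limma). REST passed the threshold under TMM rescaling, edgeR and DESeq2, each with a log2 fold change of -0.26. PHF21A fell from 20.9 ± 2.28 to 13.997 ± 1.75 RPM, MEAF6 rose from 50.5 ± 4.48 to 88.0 ± 7.58 RPM, the endocytic GTPase gene DNM2 rose 10.1-fold and the proteoglycan gene AGRN fell 9.12-fold. Which isoform of any of these genes was made cannot be read from 1 amplicon.

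Other splicing regulators were mostly higher. Of 45 tested, 32 rose, 9 fell and 4 were not called (median 0.62, and 0.50 under TMM rescaling). The neuronal regulator NOVA2 rose from 0.205 ± 0.0604 to 32.8 ± 5.65 RPM. The epithelial regulator ESRP2 fell from 15.8 ± 1.75 to 0.166 ± 0.0727 RPM, the muscle-associated RBM24 fell 179-fold and MBNL2 fell 4.87-fold. ESRP1 was near the floor in both groups, with 7 control reads and 2 SRRM4 reads (3.83-fold lower, 95% interval 0.729 to 37.8). PTBP1, the repressor of neuronal exons, had 767 ± 12.9 and 826 ± 3.11 RPM, with a log2 fold change of 0.11 ± 0.07 (adjusted p = 0.152, limma) that turned to -0.02 under TMM rescaling. Quantile normalization put it past the threshold, at 0.19. Camera gave the list an adjusted p of 0.0262, and adjusted p = 0.196 with an estimated correlation. The call was also lost with the 5 RPM filter, DESeq2 and edgeR (adjusted p = 0.05455, 0.142 and 0.15).

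Epithelial identity genes fell as a group. Of 14 tested basal epithelial genes, 13 fell and 1 rose (median -3.35, -4.27 with zeros at their bound, camera adjusted p = 1.17e-06, and adjusted p = 0.043 with an estimated correlation). S100A2 fell from 97.9 ± 4.58 to 0.166 ± 0.130 RPM, P-cadherin (CDH3) from 88.9 ± 3.36 to 0.85 ± 0.159 RPM, and the laminin-332 chain LAMB3 from 65.1 ± 3.01 to 0.561 ± 0.218 RPM. Of 26 tested epithelial junction genes, 19 fell, 5 rose and 2 were not called (median -2.15, camera adjusted p = 0.000183, and adjusted p = 0.043 with an estimated correlation). The surface protein gene EPCAM fell 207-fold and the protease inhibitor gene SPINT2 fell 46.0-fold. MAP7, a microtubule-associated protein gene in this list, rose 48.1-fold. At 1 RPM in the SRRM4 libraries were 6 of the basal genes (5 fell, 1 rose) and 15 of the junction genes (8 fell, 5 rose and 2 were not called). Without the filter the medians were -2.56 and -0.60, and both calls were kept. The same mismatch of 3 libraries with the labelled line stands beside these falls.

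Genes of luminal prostate went both ways. Of 13 tested, 4 rose, 7 fell and 2 were not called (median -0.54, camera adjusted p = 0.141, and adjusted p = 0.227 with an estimated correlation). With DESeq2 the list passed camera's test (adjusted p = 0.023), and without the filter its median was 0.03. The luminal keratins KRT8 and KRT18 fell from 260 ± 12.7 to 11.1 ± 1.03 RPM and from 353 ± 15.96 to 54.0 ± 3.66 RPM. The prostate homeobox gene HOXB13 went from 0 reads to 41.6 ± 2.69 RPM. Mesenchymal genes went both ways: of 35 tested, 14 rose, 17 fell and 4 were not called (median -0.41, camera adjusted p = 0.222, and adjusted p = 0.259 with an estimated correlation). N-cadherin (CDH2) went from 0 reads to 58.7 ± 1.42 RPM, whereas TGFBI, LOXL2 and CYR61 fell 274-fold, 42.9-fold and 59.7-fold. Markers of fibroblasts and haematopoietic cells were scarce. Genes of the embryonic kidney are in neither list and are given under the other observations. Of 15 fibroblast markers 4 reached the level for testing, of which COL1A1 rose 16.2-fold, PDGFRA rose 14.9-fold from 4 reads, COL1A2 fell at least 20.8-fold to 0 reads, and FBLN1 had 3.59 ± 0.751 and 3.61 ± 0.714 RPM (adjusted p = 0.97, limma). Of 15 haematopoietic markers only CD68 and CORO1A were tested. CD68, a lysosomal gene that epithelial cells also express, fell 10.5-fold, and CORO1A rose 2.28-fold.

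**Figure D3:**
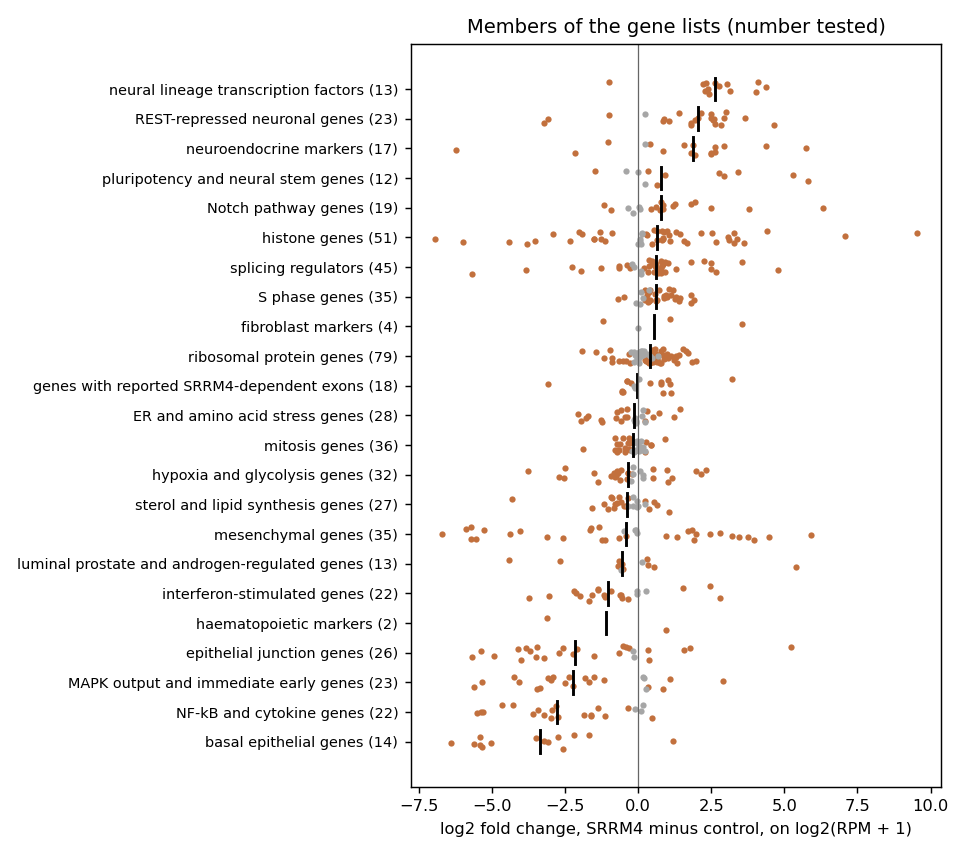
Log2 fold change (SRRM4 minus control, on log2(RPM + 1)) of each tested member of 23 gene lists, with members past an adjusted p of 0.05 coloured and a bar at each list's median. The medians run from -3.35 for basal epithelial genes to 2.64 for neural lineage transcription factors, and no median changed sign under 3 rescalings.

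Inflammatory and growth factor response genes were lower. Of 22 tested NF-kB and cytokine genes, 18 fell, 1 rose and 3 were not called (median -2.78, -2.95 with zeros at their bound, camera adjusted p = 1.17e-06, and adjusted p = 0.043 with an estimated correlation). Only 9 of these reached 1 RPM in the SRRM4 libraries (5 fell, 1 rose and 3 were not called). Without the filter the median of 28 members was -1.62 (camera adjusted p = 4.125e-06). NFKBIA, the NF-kB inhibitor that NF-kB itself induces, fell from 836 ± 13.6 to 42.0 ± 0.769 RPM. The chemokine gene IL8 fell 166-fold, TNFAIP2 fell 122-fold and the adhesion molecule gene ICAM1 fell 316-fold. Of 23 tested MAPK output and immediate early genes, 16 fell, 4 rose and 3 were not called (median -2.22, camera adjusted p = 0.000268, and adjusted p = 0.043 with an estimated correlation). In the SRRM4 libraries 18 of these reached 1 RPM (11 fell, 4 rose and 3 were not called). Without the filter the median of 27 members was -1.67 (camera adjusted p = 0.000663). PHLDA1 fell from 236 ± 12.9 to 4.81 ± 0.682 RPM, the transcription factor gene ETV5 from 96.9 ± 0.248 to 4.15 ± 0.0247 RPM, the phosphatase gene DUSP5 fell 21.0-fold and epiregulin (EREG) fell 509-fold. Of 22 tested interferon-stimulated genes, 16 fell, 3 rose and 3 were not called (median -1.02, camera adjusted p = 0.00325, and adjusted p = 0.137 with an estimated correlation). In the SRRM4 libraries 15 of these reached 1 RPM (9 fell, 3 rose and 3 were not called). Without the filter the median of 33 members was -0.54 (camera adjusted p = 0.00372). ISG15 fell 39.6-fold, and DTX3L went from 330 reads to 1, a ratio of 361 (95% interval 64.3 to 14299). LGALS3BP and IFITM1 rose 13.3-fold and 11.05-fold. Notch pathway genes were higher: of 19 tested, 13 rose, 2 fell and 4 were not called (median 0.77, camera adjusted p = 0.039, and adjusted p = 0.271 with an estimated correlation). The Notch targets HEY1 and NRARP rose 363-fold and 18.9-fold, and HES4 rose 6.77-fold.

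Genes of DNA replication were modestly higher. Of 35 tested S phase genes, 28 rose, 2 fell and 5 were not called (median 0.60, and 0.47 under TMM rescaling, camera adjusted p = 0.000546, and adjusted p = 0.043 with an estimated correlation). The replication origin factor CDT1 rose from 38.2 ± 4.67 to 136 ± 6.67 RPM, the polymerase gene POLA1 rose 3.85-fold and GINS2 rose 2.72-fold. MCM2, which dividing cells need, had 0 reads in the controls and 5 in the SRRM4 libraries, so that an amplicon at 0 reads is not by itself a silent gene (it was singled out after its value was seen). Of 36 mitosis genes, 17 fell, 5 rose and 14 were not called (median -0.17, and -0.29 under TMM rescaling). ANLN, a gene of the cytokinetic ring, fell 3.70-fold, CDC20 fell 1.74-fold, CCNB2 fell 1.55-fold and UBE2C rose 1.89-fold. Camera gave that list an adjusted p of 0.0499, and adjusted p = 0.227 with an estimated correlation. The call was also lost on leaving out any control library (0.0527, 0.0529 and 0.0554 without replicates 1, 2 and 3) or SRRM4 replicate 1 or 3 (0.0663 and 0.0522), within a range of 0.0248 to 0.227 over all alternatives.

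Histone genes moved strongly in both directions. Of 51 tested, 30 rose, 15 fell and 6 were not called (median 0.63, camera adjusted p = 0.103, and adjusted p = 0.425 with an estimated correlation). In the controls 48 of these reached 1 RPM (27 rose, 15 fell and 6 were not called). Without the filter the median of 63 members was 0.27 (camera adjusted p = 0.0784). HIST1H4E had 0 reads in every control library and 761 ± 204 RPM in the SRRM4 libraries, at least 11174-fold higher. HIST1H3J rose 186-fold, HIST1H1D rose 23.04-fold and HIST1H1B fell 243-fold. The coding sequences of replication-dependent histones are close copies, so reads can be split between members. Of 79 tested ribosomal protein genes, 47 rose, 11 fell and 21 were not called (median 0.42, and 0.34 under TMM rescaling, with 40 rising and 14 falling there). RPS7 and RPL36A rose 4.12-fold and 3.29-fold, RPL26L1 rose 2.90-fold and RPS29 fell 4.09-fold. Camera gave the list an adjusted p of 0.0159, and adjusted p = 0.227 with an estimated correlation, and processed pseudogenes share sequence with most members.

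Metabolic and stress genes fell on balance by small amounts. Of 32 tested hypoxia and glycolysis genes, 18 fell, 8 rose and 6 were not called (median -0.35, and -0.46 under TMM rescaling). The glucose transporter gene SLC2A1 fell from 721 ± 109 to 123 ± 7.6 RPM, the phosphofructokinase gene PFKP fell 5.79-fold and the mitophagy receptor gene BNIP3L fell 6.66-fold. ANGPTL4 had 574 control reads against 1, a ratio of 628 (95% interval 112 to 24839). Camera gave adjusted p = 0.039, adjusted p = 0.227 with an estimated correlation, and 0.05003 without control replicate 1 (range over all alternatives 0.0226 to 0.227). Of 27 tested sterol and lipid synthesis genes, 15 fell, 5 rose and 7 were not called (median -0.38, and -0.50 under TMM rescaling, camera adjusted p = 0.016, and adjusted p = 0.196 with an estimated correlation). The desaturase gene SCD fell from 1427 ± 73.3 to 691 ± 38.3 RPM, STARD4 fell 3.07-fold and INSIG1 rose 2.11-fold. Of 28 tested genes of endoplasmic reticulum and amino acid stress, 13 fell, 6 rose and 9 were not called (median -0.14, and -0.26 under TMM rescaling). The cystine transporter gene SLC7A11 fell 4.17-fold, the chaperone gene HSPA5 fell from 1291 ± 69.1 to 393 ± 29.8 RPM, VLDLR fell 4.95-fold, and PHGDH, of serine synthesis, rose 2.73-fold. Camera gave adjusted p = 0.0432, adjusted p = 0.208 with an estimated correlation, 0.05003 without control replicate 1 and 0.0571 without SRRM4 replicate 3 (range over all alternatives 0.0226 to 0.208).

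Adjusted over the list alone, the counts were the same as over all genes for 20 of the 23 lists. The exceptions were S phase genes (29 higher), mitosis genes (16 lower) and MAPK output genes (5 higher). Of 21 lists large enough for camera, 17 passed an adjusted p of 0.05 with the preset correlation. With an estimated one, which also lowers the degrees of freedom, 7 passed. Those 7 were the REST-repressed, neural transcription factor, basal, junction, S phase, NF-kB and MAPK lists. Other lists lost their call with the 5 RPM filter (neuroendocrine, mitosis, hypoxia and stress), DESeq2 (neuroendocrine, interferon, mitosis and stress), edgeR (ribosomal, mitosis, hypoxia and stress) or quantile normalization (stem cell, Notch, mitosis, hypoxia and stress). The mitosis and stress lists also lost it without a mean-variance trend. With DESeq2 the mesenchymal and histone lists gained a call (adjusted p = 0.00758 and 0.00602), as did the histone list with the 5 RPM filter (0.0353).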

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

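The alternatives were set down as planned, but edgeR and DESeq2 on recovered reads could be run only once the values were seen to be whole reads. The number of changed genes, 10009, lay between 8371 (genes of at least 5 RPM, fewer tested) and 11191 (no filter, more tested) over the other settings. It was 10205 of 13197 genes with edgeR, 9654 with DESeq2, 9900 with TMM rescaling, 8842 at an adjusted p below 0.01, and 9509 to 9802 on leaving out any 1 library. The count of genes changed at least 2-fold, 4478, fell to 2875 with a pseudocount of 5, which by construction shrinks fold changes of low genes. It was 3542 to 5242 under the remaining settings. Same-numbered libraries of the groups did not deviate together (correlations 0.00648, 0.00944 and 0.167), so the numbers do not pair them. The replicate block gave 10093 changed genes, and only replicate 3 of the controls correlated best with its own number. SRRM4 stayed past the threshold in the same direction under each setting. Of 2255 values of 119 named genes under alternatives, 2239 kept direction and side of the threshold, 4 newly passed it (REST in 3 settings, PTBP1 in 1) and 12 crossed 0 without a call (FBLN1 and PTBP1). Of 420 list values, 42 lost a call, 4 gained one and none reversed. Lists losing calls most often were mitosis (11 of 20 settings), endoplasmic reticulum stress (8) and hypoxia and glycolysis (5). All 3 libraries of the SRRM4 group share the doubt about identity raised under the other observations, so no count can be given without them. At this depth and with 3 libraries per group, 62% of simulated 1.5-fold changes were recovered. In that simulation 12319 of 12519 tested genes were unchanged, whereas 78.7% were called in the data. The recovered share therefore does not carry over to this comparison.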

Other observations

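Beyond the lists, 43 genes had 0 reads in every control library and at least 20 RPM in every SRRM4 library, whereas 0 genes showed the opposite. Both counts leave out the Y-linked genes and the X-inactivation transcripts, so they do not cover the whole panel. The genes named here were chosen after their values were seen. They include the homeobox gene CDX2 (76.5 RPM), the paired-box gene PAX3 (45.3 RPM), the zinc finger gene SALL1 (48.9 RPM) and cyclin D2 (CCND2, 61.3 RPM). The cancer-testis gene MAGEA6 reached 92.0 RPM, though close relatives can share its reads. Broadly expressed genes were also among the 43. ATG5, an autophagy gene of which DU145 cells are known to make no functional protein, had 44.0 ± 4.01 RPM (SD, n = 3) in the SRRM4 libraries, and CHAMP1, a gene of chromosome alignment, had 42.3 ± 5.07 RPM.

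Changes also followed chromosomes. The median log2 fold change of tested genes was -0.45 on chromosome 18 and -0.39 on chromosome 8, against 0.56 on chromosome 20 and 0.66 on chromosome 22. A list of 15 genes of the embryonic kidney and of HEK293 cells was written after IRS4, LIN28B and HOXD13 had been seen among the rises. Of its members 12 reached 1 RPM in a group and 0 belong to another list. Of the 12, 8 were at least 4-fold higher, against 10.4% of the 12962 genes at 1 RPM in a group. Of the 8 above 1 RPM in the controls, 4 were at least 4-fold higher, 1 was at least 4-fold lower and 3 were neither. EYA1, HOXD11 and WT1 went from 0 reads to 10.4, 5.87 and 6.18 RPM, SIX2 rose 102-fold and BEX1 rose 16.4-fold. OSR1 was 0.156 times its control level, and CKB, the most abundant member, differed little (1088 ± 116 and 1205 ± 358 RPM, SD, n = 3). PAX2 went from 0 to 39 reads (0.808 RPM, at least 11.9-fold higher), and PAX8 had 0 reads in both groups.

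Of the tests that follow, the test of scaling, both tests on residual transcripts and the splits were chosen after the result was seen. The tests on neighbouring genes and on the kidney list had their limits set before their own values were computed, but after the table of genes had been seen.

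The first pattern is that 78.7% of tested genes differed between groups of tight replicates. Scaling of the RPM values is argued against, since 9654 or more genes changed under 5 other scalings or tools. Regulation within an unchanged genome and another genome in the SRRM4 libraries cannot be told apart by neighbouring genes: medians over blocks of 50 and 100 varied 2.47 and 3.23 times as much as after shuffling gene order (permutation p = 0.001 for both, the smallest that 1000 shuffles can give), against 1.05 and 1.21 between control replicates (p = 0.153 and 0.009) and 1.1 and 1.22 between SRRM4 replicates (p = 0.015 and 0.001). The limit of 2 set earlier against regulation was wrong, because shuffling removes shared regulation of neighbours as well as copy number. Also left open are 293T packaging cells, as 8 of 12 measured kidney list members were at least 4-fold higher. But the list was written late, and members absent from the controls counted only if they rose. Another line and a changed DU145 subline stay open as well. SRRM4 acting alone in unchanged DU145 cells is argued against by the 3 of 6 libraries that did not match the labelled line. Whether SRRM4 added to the differences cannot be told from these libraries.

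The second pattern is that transcripts abundant in the controls persisted at a small share in the SRRM4 libraries. Of 2223 genes with at least 100 RPM in the controls, 19 were under 0.5% of that level, with a median of 0.287% (0.244%, 0.271% and 0.294% in SRRM4 libraries 1, 2 and 3) and a lowest value of 0.0868% for LOC100507127 (95% counting interval 0.0282 to 0.203). Reads misassigned equally in both directions between pooled libraries are argued against, because that lowest share in reverse would give 42 reads of SRRM4 and HIST1H4E in the controls, and 0 were seen. A small share of control-type RNA or cells in the SRRM4 libraries and low expression of each gene in the SRRM4 cells themselves both stay open. That 43 of 72 genes switched off in the controls were at 0 reads but 0 of 74 switched off in the SRRM4 libraries were (Fisher's exact p = 5.84e-18, two-sided) restates the pattern in genes chosen for it and does not tell these apart. Y-linked genes and X-inactivation transcripts are not among the genes counted for this pattern.

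Whether chance made the groups differ cannot be assessed from the splits, because the 6 libraries form only 10 splits and no share under 0.05 is possible. The real split, 1 of the 10, gave 10009 changed genes (5645 higher, 4364 lower, 4478 at least 2-fold). The highest of the other splits gave 0 for each of these counts by limma, with at most 47 genes at an unadjusted p under 0.05, and 0 by edgeR. Each other split has libraries of both groups on both sides, so the real difference inflates the spread there and removes calls. The counts of 0 therefore say nothing about chance.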
